A study of Mus musculus with 12 samples.

How the data were processed

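Choroid plexus tissue was dissected from mice of the B6 strain at 4 ages: E12.5, P0, P14 and A6m (6 months). Per the labels, tissue went straight into Trizol, total RNA was extracted, libraries were made with a Kapa mRNA HyperPrep kit and sequenced as 100 bp paired ends, with 3 or 4 independent specimens per datapoint. The labels name neither the sex of the animals, nor the ventricle the tissue came from, nor a sequencing batch. The table has 52459 gene symbols, and 12 of its columns were mapped to the 4 ages with 3 libraries each. A further 7 columns were not used here, and mutant choroid plexus was not analysed here.

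The values are TPM (transcript abundances scaled to a fixed sum) that the authors computed with kallisto on GRCm38, as the submitters' processing notes list them, without a version. The annotation release and the step from transcripts to genes are not stated. TPM adjusts for transcript length and sets every library to the same sum, so that a rise of a few abundant transcripts lowers the values of all others. TPM keeps no read counts, so the depth per library is unknown, and no counting interval, detection floor or count model was applied. A value of 0 is therefore given as listed at 0.

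Gene symbols were looked up in GENCODE M21 for coordinates and chromosomes, and 96.8% of the tested symbols were found there. Genes entered the tests when TPM was at least 1 in at least 3 of the 12 libraries, which left 17422, of which 116 had values identical to those of another symbol. Each value became log2(TPM + 1). The main test was limma 3.58.1 in R 4.3.3, with an intensity-dependent prior (eBayes with trend), fitted to the 12 libraries as 4 group means with 8 residual degrees of freedom, because 3 libraries per age give little information on spread by themselves. Calls are at a Benjamini-Hochberg adjusted p under 0.05, and every adjusted p of a gene comes from limma. The comparisons were P0 against E12.5, P14 against P0, A6m against P14 and A6m against E12.5, with a moderated F-test over the 4 ages and counts of genes that rose into P0 or P14 and fell after it. On simulated data made from these values, 83% to 87% of genes changed by 1 on the log2 scale and 93% to 97% of those changed by 2 were recovered, with 6 to 12 false calls per comparison. The simulation used independent noise and changed 100 of the 17422 genes by each size, none near the floor, without a shift of all genes. The real comparisons differ in these respects, so the figures do not give the performance on them.

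A set of 34 gene lists was fixed before the data were examined, as were the tests of the comparisons and the rule for naming genes. Lists with at least 5 tested members, 33 of them, were tested against all other genes with camera from limma at a preset inter-gene correlation of 0.01, adjusted over the lists. Camera was repeated with a correlation estimated per list, and fry was run as a test of each list alone, both on the values as deposited. Fry does not set a list against other genes, so a shift of all genes enters its calls. Rose and fell refer to genes that passed the limma test. Counts given over the list alone adjust p among the members of that list only. With an estimated correlation, p was also adjusted over the lists. Named genes were the 5 with the largest rise and the 5 with the largest fall per comparison among called genes with a mean of at least 20 TPM in the higher age and no overlap between the libraries of both ages. Unnamed gene models, pseudogenes and mitochondrially encoded genes were left out of that choice. To these were added up to 4 called members per described list with the largest absolute difference, from which the text prints a part and some are not reported here, and 8 genes named in every comparison (Ttr, Aqp1, Folr1, Mki67, Igf2, Shh, Otx2 and Gmnc).

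The alternatives tried were pseudocounts of 0.1 and 5, no filter, a mean of at least 5 TPM, median-of-ratios scaling over the 19075 genes above 0 in all 12 libraries, quantile normalization, rescaling without the 10 most abundant genes, only the 6 libraries of a comparison, limma array quality weights, the replicate number as a block, each library left out in turn, and limma treat against a 1.5-fold difference. After the data were seen, 2 more were added for the counts, without 8 ribosomal RNA-associated and small-RNA features and without genes of the X and Y chromosomes. List medians were also recomputed with scaling, without those 8 features, and without E12.5 replicate 1, E12.5 replicate 2 or A6m replicate 3. Other splits of the same libraries were counted, all 10 per pair of ages and 100 drawn for the tests over more ages. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.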

Results

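The 12 libraries profiled choroid plexus, the secretory epithelium with its vascular stroma that makes cerebrospinal fluid in the brain ventricles, dissected from B6 mice at an embryonic stage (E12.5), on the day of birth (P0), at postnatal day 14 (P14) and at 6 months (A6m). Values are TPM as mean ± SD over 3 libraries per age. Transcripts of Ttr, which encodes the thyroid hormone carrier transthyretin, took 1.54% ± 0.503 of all TPM at E12.5, 14.2% ± 0.107 at P0, 16.2% ± 0.894 at P14 and 14.1% ± 0.460 at A6m. Mitochondrially encoded transcripts took 13.9% ± 3.41, 21.2% ± 1.28, 30.7% ± 1.95 and 32.6% ± 1.40 at the same ages, and globin transcripts 6.00% ± 0.392, 1.02% ± 0.342, 0.0844% ± 0.00656 and 0.0347% ± 0.0208. Pearson's r across the tested genes on the log2 scale, over genes that are not independent replicates, was 0.959 to 0.964 between E12.5 libraries and 0.977 to 0.978 between A6m libraries, against 0.767 to 0.790 between E12.5 and A6m. The first principal component carried 66.01% of the variance and the next 12.6%.

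Several libraries stood apart in ways the ages do not name. In E12.5 replicate 1, 8 ribosomal RNA-associated and small-RNA features took 16.3% of TPM, against 2.44% and 3.25% in the other E12.5 libraries. Xist, transcribed from the inactive X chromosome of females, was at 149 to 155 TPM in the 3 A6m libraries and at 0.389 TPM in E12.5 replicate 2, and no P0 or P14 library exceeded 0.809 TPM. Ddx3y, on the Y chromosome, was at 80.1 to 117 TPM in every P0 and P14 library and at 0.122 to 0.366 TPM at A6m. E12.5 replicates 1 and 3 held both transcripts, Xist at 139 and 89.5 TPM and Ddx3y at 9.26 and 50.9 TPM. The labels give no sex, so every comparison of A6m with another age also set libraries with Xist against libraries with transcripts of the Y chromosome. Against E12.5 that split was less complete, because E12.5 replicates 1 and 3 held Xist as well. Through these replicates P0 against E12.5 also differed in Xist.

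**Figure D1:**
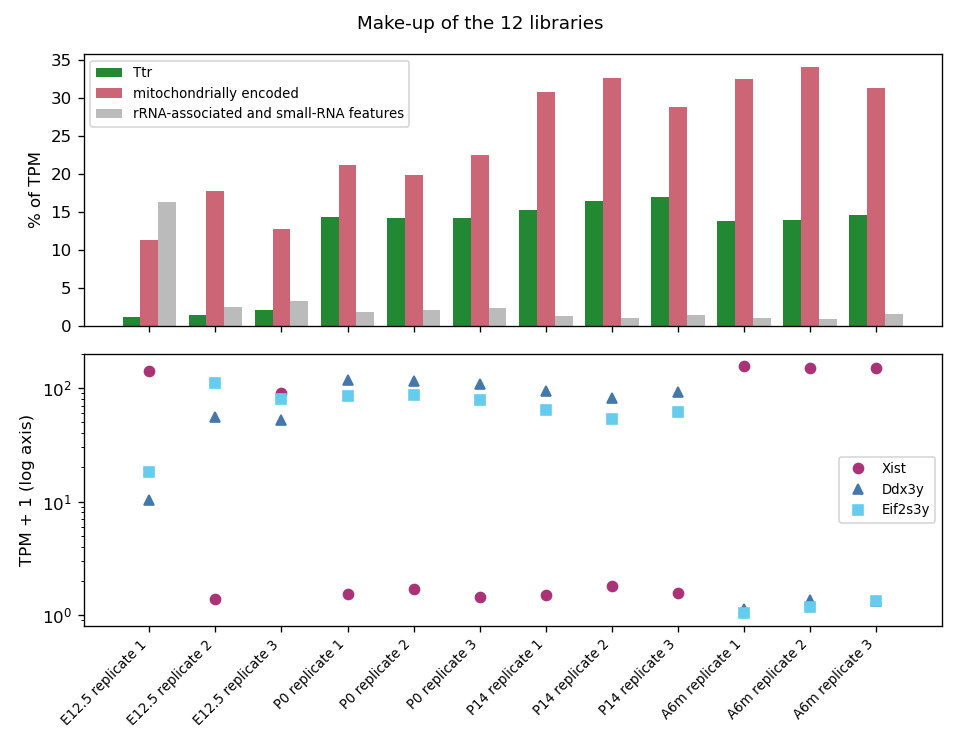
Make-up of the 12 libraries: the upper panel plots the percent of TPM taken by Ttr, by mitochondrially encoded transcripts and by 8 ribosomal RNA-associated and small-RNA features, and the lower panel TPM + 1 of Xist, Ddx3y and Eif2s3y on a log axis, with 1 bar or point per library. Ttr rose from 1.54% at E12.5 to 14.2% at P0, and only the A6m libraries had high Xist with Y-chromosome transcripts under 1 TPM.

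The deposited TPM of most genes drifted downward with age. The median log2 difference over all 17422 tested genes was -0.27 from E12.5 to P0, -0.41 from P0 to P14, -0.04 from P14 to A6m and -0.71 from E12.5 to A6m. Median-of-ratios scaling, called scaling from here on, brought these medians to -0.02, 0.00, -0.00 and -0.01. Rescaling without the 10 most abundant genes left -0.02, -0.26, -0.06 and -0.33, which removed most of the drift from E12.5 to P0 but only a part from P0 to P14 and from E12.5 to A6m. The limma test called 10848 genes between P0 and E12.5 (3233 higher and 7615 lower at P0, 29.8% higher), and 48.3% of calls were higher with scaling. Between P14 and P0 it called 10244 (928 higher, 9316 lower, 9.06% higher), against 53.4% higher with scaling. Between A6m and P14 it called 3642 (1530 higher, 2112 lower, 42.0% higher), against 52.1% with scaling, and between A6m and E12.5 13446 (2648 higher, 10798 lower, 19.7% higher), against 49.7% with scaling. Scaling also turned calls: 0, 375, 0 and 1307 genes in the 4 comparisons were called on both scales in opposite directions. In the same direction on both scales were 8628, 4379, 3496 and 8877. At least a 2-fold difference was reached by 1228 higher and 2569 lower genes, 222 and 1764, 365 and 443, and 1290 and 6406, in the same order. With scaling, which by construction centres the genes near 0, these were 1617 higher and 1625 lower genes, 524 and 708, 414 and 496, and 2819 and 2998. Over the 4 ages together the limma F-test called 14829 of 17422 genes (85.1%).

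**Figure D2:**
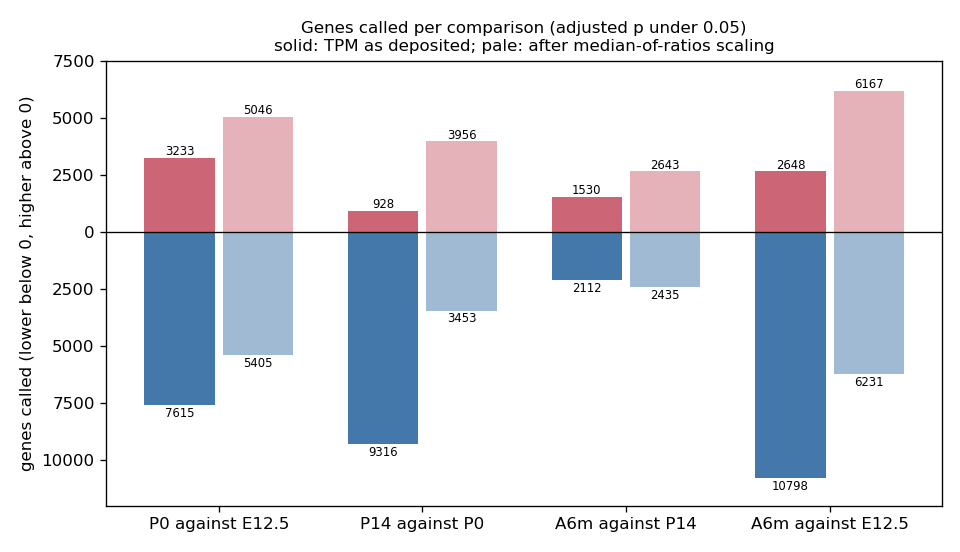
Number of genes called per comparison at adjusted p under 0.05, higher above and lower below 0, from TPM as deposited (solid bars) and after scaling (pale bars). As deposited, 928 genes were higher and 9316 lower at P14 than at P0; after scaling 3956 were higher and 3453 lower.

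Between E12.5 and birth the epithelial transcripts of the choroid plexus rose while those of dividing cells and of the program that builds multiciliated cells fell. Ttr rose from 15444 ± 5032 to 141944 ± 1066 TPM (9.19-fold, log2 difference 3.25, adjusted p = 1.78e-07) and Folr1, a folate receptor, from 262 ± 55.5 to 1415 ± 33.6 TPM (log2 difference 2.45, adjusted p = 3.93e-08). The proliferation marker Mki67 fell from 89.2 ± 10.6 to 7.36 ± 0.160 TPM (log2 difference -3.43, adjusted p = 5.44e-09). Mcidas, a coregulator that starts the multiciliated cell program, fell from 37.0 ± 4.10 to 3.85 ± 0.475 TPM (log2 difference -2.97, adjusted p = 1.39e-08).

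Among 31 tested genes of the choroid plexus epithelium list, 25 of 31 members rose and 2 fell (26 and 2 over the list alone), with a median log2 difference of 1.95, or 2.19 with scaling (camera adjusted p = 3.48e-16, estimated-correlation adjusted p = 0.275). Tmem72 rose from 4.29 ± 2.11 to 140.0 ± 5.90 TPM, Kl, which encodes the fibroblast growth factor coreceptor Klotho, from 1.28 ± 0.335 to 52.2 ± 3.54 TPM, and Ace, the angiotensin-converting enzyme, from 14.5 ± 4.30 to 283 ± 14.6 TPM. In the list of ion and water transport 22 of 35 members rose and 4 fell (23 and 4 over the list alone, camera adjusted p = 8.20e-09, estimated-correlation adjusted p = 0.362), and 7 fell without E12.5 replicate 1. The water channel gene Aqp1 rose from 189 ± 91.8 to 654 ± 8.10 TPM (log2 difference 1.91, adjusted p = 8.65e-05), the cation channel gene Trpv4 from 0.974 ± 0.311 to 44.4 ± 2.99 TPM and the calcium pump gene Atp2b3 from 12.7 ± 7.91 to 228 ± 10.3 TPM. Of the organic solute transporters 27 of 37 members rose and 5 fell (28 and 5 over the list alone, camera adjusted p = 3.43e-12, estimated-correlation adjusted p = 0.275), among them Slc6a20a, a transporter of proline, from 1.05 ± 0.50 to 82.1 ± 9.92 TPM. In the epithelial junction list 14 of 22 members rose and 4 fell (same over the list alone, camera adjusted p = 9.15e-05, estimated-correlation adjusted p = 0.343): the tight junction gene Cldn2 rose from 36.4 ± 1.56 to 219 ± 9.53 TPM. Cdh2, encoding N-cadherin, fell from 72.1 ± 16.5 to 15.7 ± 0.198 TPM.

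Genes of energy metabolism were higher at P0. Nuclear-encoded oxidative phosphorylation genes had a median log2 difference of 0.31 (camera adjusted p = 2.24e-10, estimated-correlation adjusted p = 0.393), where 34 of 60 members rose and 1 fell (same over the list alone) and 51 rose and 0 fell after scaling. In the glycolysis list 14 of 17 members rose and 1 fell (same over the list alone, camera adjusted p = 8.20e-09, estimated-correlation adjusted p = 0.275). The phosphofructokinase gene Pfkp rose from 13.3 ± 2.41 to 81.2 ± 4.78 TPM. Cholesterol synthesis genes went the other way, since 0 of 24 members rose and 22 fell (same over the list alone, camera adjusted p = 1.05e-04, estimated-correlation adjusted p = 0.275).

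In the proliferation list 0 of 42 members rose and 42 fell (same over the list alone), with a median log2 difference of -2.91 (camera adjusted p = 1.11e-16, estimated-correlation adjusted p = 0.275). The topoisomerase gene Top2a fell from 181 ± 4.29 to 14.3 ± 1.48 TPM and Birc5 from 73.7 ± 7.95 to 5.36 ± 0.113 TPM. Among regulators of the multiciliated cell fate 1 of 17 members rose and 16 fell (same over the list alone, camera adjusted p = 1.11e-04, estimated-correlation adjusted p = 0.275). Ccno fell from 47.2 ± 5.92 to 4.69 ± 0.388 TPM and Deup1, which builds the deuterosomes that amplify centrioles, from 121 ± 8.67 to 14.9 ± 0.571 TPM, while Gmnc, upstream of Mcidas, fell less, from 128 ± 23.3 to 92.4 ± 4.71 TPM (log2 difference -0.45, adjusted p = 0.00403, and -0.16 with scaling, where its adjusted p was 0.105, or 0.174 without the 10 most abundant genes). In the motile axoneme list 2 of 62 members rose and 50 fell (same over the list alone). By member, 3 rose and 46 fell after scaling (as deposited, camera adjusted p = 1.81e-06, estimated-correlation adjusted p = 0.463). Dnah7a, a dynein heavy chain gene, fell from 48.8 ± 4.74 to 5.08 ± 1.28 TPM and Spag17 from 22.1 ± 4.51 to 4.83 ± 0.718 TPM. The dynein assembly factors moved alike, since 0 of 13 members rose and 12 fell (same over the list alone, camera adjusted p = 0.00155, estimated-correlation adjusted p = 0.459). The signal molecule gene Shh fell from 19.7 ± 4.11 to 5.87 ± 0.302 TPM (log2 difference -1.57, adjusted p = 2.73e-06), and Gli1, a target of its pathway, from 18.5 ± 0.158 to 2.06 ± 0.761 TPM. The Hedgehog list itself was not called: 0 of 14 members rose and 9 fell (same over the list alone, camera adjusted p = 0.0571). Otx2, a transcription factor gene of the choroid plexus, was at 463 ± 99.95 and 559.9 ± 12.3 TPM (log2 difference 0.30, adjusted p = 0.0580), against an adjusted p of 4.18e-05 with scaling, 8.20e-04 without the 10 most abundant genes, 0.0131 with quantile normalization and 0.00471 without E12.5 replicate 3. Igf2 rose from 1079.6 ± 16.9 to 1264 ± 54.6 TPM (log2 difference 0.23, adjusted p = 0.0179), a call lost without P0 replicate 3 (adjusted p = 0.0711).

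Some markers of cells outside the epithelium also moved. The lists of fibroblasts and matrix, macrophages and mural cells were not called (camera adjusted p = 0.979, 0.568 and 0.460), with 6, 4 and 3 members rising and 12, 12 and 4 falling. Erythroid transcripts fell, as 1 of 14 members rose and 13 fell (same over the list alone, camera adjusted p = 7.82e-05, estimated-correlation adjusted p = 0.362). The embryonic globin genes held the largest falls under the naming rule, Hbb-y from 24778 ± 4462 to 6.97 ± 0.855 TPM, Hba-x from 7065 ± 408 to 1.97 ± 0.326 TPM and Hbb-bh1 from 3907 ± 1904 to 1.22 ± 0.592 TPM, followed by Hsd3b6 from 83.4 ± 16.6 to 0.0166 ± 0.0287 TPM and the blood group gene Kel from 52.5 ± 12.6 to 0.153 ± 0.0735 TPM. Endothelial markers fell in 18 of 19 cases (same over the list alone; camera adjusted p = 0.00200, estimated-correlation adjusted p = 0.463). Interferon-response genes rose, as 19 of 24 members rose and 0 fell (same over the list alone, camera adjusted p = 1.45e-09, estimated-correlation adjusted p = 0.343), among them Ifit3 from 1.53 ± 0.455 to 18.1 ± 8.03 TPM and Ifi27 from 8.73 ± 0.933 to 51.1 ± 4.76 TPM. The largest rises under the naming rule were those of Ppp1r1b, encoding the phosphatase inhibitor DARPP-32, from 1.95 ± 0.360 to 159 ± 6.10 TPM, the metallothionein gene Mt3 from 6.30 ± 1.91 to 305 ± 18.1 TPM, Slc6a20a, the neutrophil gene S100a9 from 0.184 ± 0.163 to 46.9 ± 2.36 TPM, and the sulfotransferase gene Sult1a1 from 1.53 ± 0.806 to 93.4 ± 6.47 TPM. Camera called 21 of 33 lists (10 up, 11 down), and none with an estimated correlation, where 4 lists had an unadjusted p under 0.05 and fry called 31. A 1.5-fold minimum (limma treat) left 3983 called genes.

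From birth to P14 some epithelial transcripts rose further, and matrix, endothelial and imprinted growth genes fell on both scales. At the preset correlation camera placed the transport lists above other genes on both scales, but not at an estimated correlation (adjusted p = 0.764 and 0.734). Prlr, the prolactin receptor gene, rose from 1.995 ± 0.551 to 135 ± 18.4 TPM (log2 difference 5.51, adjusted p = 5.55e-09). Kl rose from 52.2 ± 3.54 to 480.2 ± 46.2 TPM (log2 difference 3.18, adjusted p = 2.48e-08). Gpc3, a glypican gene linked to growth control, fell from 476 ± 30.5 to 15.4 ± 1.21 TPM (log2 difference -4.87, adjusted p = 1.40e-07), and H19, an imprinted noncoding RNA gene, from 334 ± 25.01 to 12.2 ± 2.41 TPM (log2 difference -4.68, adjusted p = 2.15e-06). Ttr did not pass the test, at 141944 ± 1066 and 161624 ± 8940.4 TPM (log2 difference 0.19, adjusted p = 0.438). With scaling it was not called either (0.70, adjusted p = 0.124). Its libraries of the 2 ages did not overlap, as for 69.3% of all tested genes. The fit shares 1 spread over the ages, and that of Ttr was wide at E12.5 (15444 ± 5032 TPM), so the lack of a call does not show that Ttr was unchanged.

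In the choroid plexus epithelium list 12 of 31 members rose and 6 fell (same over the list alone) as deposited. By member, 20 rose and 2 fell after scaling (as deposited, camera adjusted p = 1.11e-11, estimated-correlation adjusted p = 0.413). Without E12.5 replicate 1, 11 fell as deposited. Enpp2, encoding the secreted lysophospholipase autotaxin, rose from 3137 ± 125 to 22527 ± 1398 TPM and Cox8b, a cytochrome c oxidase subunit gene, from 0.223 ± 0.386 to 20.3 ± 4.33 TPM. The other largest rises under the naming rule were those of the neurofilament gene Nefh from 0.420 ± 0.191 to 28.8 ± 3.94 TPM, Ppp2r2c from 1.62 ± 0.349 to 42.2 ± 1.43 TPM and Nav3 from 3.38 ± 0.608 to 54.5 ± 9.27 TPM. Ion and water transport genes went both ways: 5 of 35 members rose and 15 fell (same over the list alone), and 16 rose and 6 fell after scaling. Their median was -0.27 and camera placed them above other genes (camera adjusted p = 0.0257, estimated-correlation adjusted p = 0.764). Aqp1 fell from 654 ± 8.10 to 296 ± 18.0 TPM (log2 difference -1.14, adjusted p = 0.00367). Among organic solute transporters 8 of 37 members rose and 11 fell (8 and 10 over the list alone), with a median of -0.25 and a camera call upward (camera adjusted p = 0.00776, estimated-correlation adjusted p = 0.734). With scaling, which lifts nearly all genes at this step, 17 rose and 8 fell (median 0.26), and the camera direction stayed up (adjusted p = 0.0414). The thyroxine transporter gene Slco1c1 rose from 87.6 ± 4.20 to 263 ± 22.1 TPM. Slc6a13 fell from 20.8 ± 3.94 to 2.48 ± 1.54 TPM. Folr1 was at 1415 ± 33.6 and 1357 ± 51.8 TPM (adjusted p = 0.680, log2 difference -0.06 as deposited and 0.45 with scaling).

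Oxidative phosphorylation genes showed how far the scale mattered: 16 of 60 members rose and 1 fell (9 and 0 over the list alone) as deposited. By member, 57 rose and 0 fell after scaling (as deposited, camera adjusted p = 2.73e-17, estimated-correlation adjusted p = 0.385). Cycs, encoding cytochrome c, rose from 32.5 ± 2.69 to 60.2 ± 2.50 TPM, and Ndufa1, encoding a subunit of complex I, from 456 ± 25.5 to 664 ± 37.1 TPM. Cholesterol synthesis genes had 5 members up and 7 down of 24 (same over the list alone), and 15 rose and 0 fell after scaling. Their median was -0.09 and the camera direction up (camera adjusted p = 0.00910, estimated-correlation adjusted p = 0.630). Glycolysis genes had a median of -0.07 and the same camera direction (camera adjusted p = 0.0170, estimated-correlation adjusted p = 0.734), and 3 of 17 members rose and 5 fell (same over the list alone). With scaling 8 rose and 0 fell (median 0.42).

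All 19 members of the imprinted growth network fell as deposited, and 15 after scaling (same over the list alone; camera adjusted p = 5.50e-07, estimated-correlation adjusted p = 0.385). Peg10 fell from 34.2 ± 0.802 to 4.33 ± 0.194 TPM and Meg3 from 364 ± 68.5 to 86.3 ± 12.2 TPM. Igf2 fell from 1264 ± 54.6 to 1074 ± 93.1 TPM as deposited (log2 difference -0.24, adjusted p = 0.0157), but its log2 difference was 0.28 with scaling (adjusted p = 0.0510) and -0.03 without the 10 most abundant genes (adjusted p = 0.738). The call was also lost without P0 replicate 3 (adjusted p = 0.0612) or P14 replicate 2 or 3 (adjusted p = 0.0618 and 0.0620). Proliferation genes fell further, 38 of 42 (0 and 39 over the list alone; camera adjusted p = 3.45e-08, estimated-correlation adjusted p = 0.385). Mki67 went from 7.36 ± 0.160 to 1.58 ± 0.251 TPM (log2 difference -1.70, adjusted p = 2.40e-06). Among multiciliated cell regulators 0 of 17 members rose and 16 fell (same over the list alone, camera adjusted p = 6.21e-04, estimated-correlation adjusted p = 0.385). Mcidas went from 3.85 ± 0.475 to 0.597 ± 0.136 TPM and Gmnc from 92.4 ± 4.71 to 61.2 ± 4.59 TPM (log2 difference -0.59, adjusted p = 0.00100, and -0.08 with scaling, adjusted p = 0.475). In the motile axoneme list 1 of 62 members rose and 48 fell (1 and 51 over the list alone) as deposited. By member, 8 rose and 25 fell after scaling (as deposited, camera adjusted p = 0.00780, estimated-correlation adjusted p = 0.764). Ccdc40 fell from 34.1 ± 1.92 to 5.38 ± 0.423 TPM and Tekt2 from 19.7 ± 1.82 to 3.38 ± 0.960 TPM. In the Hedgehog list 0 of 14 members rose and 12 fell (same over the list alone, camera adjusted p = 0.00780, estimated-correlation adjusted p = 0.734). Shh fell from 5.87 ± 0.302 to 0.128 ± 0.0525 TPM (log2 difference -2.61, adjusted p = 6.11e-07). Otx2 fell from 559.9 ± 12.3 to 387 ± 7.02 TPM as deposited (log2 difference -0.53, adjusted p = 0.00389), against -0.02 with scaling (adjusted p = 0.874) and -0.16 with quantile normalization (adjusted p = 0.251).

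Markers of several other cell types fell, but not of all. Of the oligodendrocyte markers 3 of 7 members rose and 2 fell (same over the list alone), with a camera call upward (camera adjusted p = 0.00776, estimated-correlation adjusted p = 0.385) that was lost with scaling (adjusted p = 0.357). Of the mural cell markers 1 of 10 members rose and 5 fell (same over the list alone, camera adjusted p = 0.850). In the endothelium list 0 of 19 members rose and 19 fell (same over the list alone, camera adjusted p = 4.13e-05, estimated-correlation adjusted p = 0.630). Cdh5, encoding VE-cadherin, fell from 38.0 ± 2.98 to 6.45 ± 0.983 TPM. In the list of fibroblasts and matrix 2 of 22 members rose and 19 fell (same over the list alone, camera adjusted p = 0.0167, estimated-correlation adjusted p = 0.734). The fibronectin gene Fn1 fell from 69.5 ± 6.93 to 10.5 ± 5.17 TPM. Of the macrophage markers 0 of 26 members rose and 23 fell (same over the list alone, camera adjusted p = 0.00648, estimated-correlation adjusted p = 0.734), and 15 fell after scaling. F13a1 fell from 14.3 ± 0.480 to 1.47 ± 0.108 TPM. In the interferon-response list 1 of 24 members rose and 21 fell (same over the list alone, camera adjusted p = 0.0304, estimated-correlation adjusted p = 0.764), and the list call was lost without E12.5 replicate 1 (adjusted p = 0.0674) or without the 8 ribosomal RNA-associated features (adjusted p = 0.0505). Isg15 fell from 15.7 ± 6.06 to 1.75 ± 0.259 TPM, while Ifi27 rose from 51.1 ± 4.76 to 219 ± 31.6 TPM. Further large falls under the naming rule were those of Penk, encoding proenkephalin, from 659.5 ± 62.1 to 8.67 ± 1.83 TPM, the kallikrein gene Klk4 from 94.1 ± 4.34 to 1.72 ± 0.183 TPM, and the microRNA gene Mir351, which went from 26.9 ± 22.8 TPM to a listed value of 0 in all 3 P14 libraries. Mir351 is annotated from 53053255 to 53053353, a span shorter than a read of 100 bp, so its TPM may rest on few reads. Camera called 20 of 33 lists (9 up, 11 down), none with an estimated correlation, where 2 had an unadjusted p under 0.05 and fry called 26. Of the lists that camera called up, fry called only choroid plexus epithelium (fry adjusted p = 0.00189) and mitochondrially encoded genes (0.0144). It did not call ion and water transport (0.12), organic solute transporters (0.0998), oxidative phosphorylation (0.077), glycolysis, cholesterol synthesis, neurons or oligodendrocytes. Fry was run on deposited values only, where the median of all genes was -0.41 at this step. It thus cannot separate a list from that drift, which hinders calls upward and favours calls downward. Immediate early genes, for example, were called down by fry, while their camera direction was up without a call. A 1.5-fold minimum (limma treat) left 1626 called genes.

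Between P14 and 6 months interferon-response and cholesterol synthesis genes rose, and endothelial, mural and matrix genes fell. Scd1, encoding the stearoyl-CoA desaturase, rose from 6.16 ± 1.21 to 124 ± 9.38 TPM (log2 difference 4.13, adjusted p = 1.66e-07), and H2-Aa, a class II major histocompatibility gene, from 0.636 ± 0.104 to 31.6 ± 10.01 TPM (log2 difference 4.27, adjusted p = 4.34e-07). Col3a1, a fibrillar collagen gene, fell from 38.9 ± 5.27 to 3.09 ± 0.967 TPM (log2 difference -3.31, adjusted p = 4.96e-07). The tissue's most abundant nuclear transcript, Ttr, was at 161624 ± 8940.4 and 141048 ± 4602 TPM (adjusted p = 0.558). Its libraries of the 2 ages did not overlap here either, as for 44.3% of all tested genes.

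In the interferon-response list 20 of 24 members rose and 0 fell (21 and 0 over the list alone), with a median log2 difference of 1.36 (camera adjusted p = 1.70e-14, estimated-correlation adjusted p = 0.248). Ifit1 rose from 1.46 ± 0.481 to 21.9 ± 11 TPM and Bst2, encoding the antiviral protein tetherin, from 42.0 ± 3.09 to 203 ± 30.9 TPM. For class I antigen presentation 6 of 15 members rose and 0 fell (7 and 2 over the list alone, camera adjusted p = 4.24e-04, estimated-correlation adjusted p = 0.376), among them H2-K1 from 25.9 ± 2.12 to 53.5 ± 6.17 TPM. Macrophage markers went both ways: 4 of 26 members rose and 9 fell (5 and 10 over the list alone), and the rises were led by the class II genes H2-Eb1 from 0.480 ± 0.190 to 19.4 ± 6.45 TPM, Cd74 from 2.40 ± 0.442 to 41.3 ± 14.4 TPM and H2-Ab1 from 0.427 ± 0.192 to 14.1 ± 5.03 TPM, beside H2-Aa. The list's median was -0.25 and its mean 0.19 (camera adjusted p = 0.461). Without A6m replicate 3 the median was -0.46 (camera adjusted p = 0.0799).

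Of the cholesterol synthesis genes 17 of 24 members rose and 0 fell (20 and 0 over the list alone). By member, 19 rose and 0 fell after scaling (as deposited, camera adjusted p = 4.07e-13, estimated-correlation adjusted p = 0.137). Fdps rose from 25.4 ± 1.61 to 57.0 ± 2.31 TPM and Idi1 from 16.4 ± 1.54 to 36.5 ± 2.32 TPM. In the choroid plexus epithelium list 9 of 31 members rose and 4 fell (10 and 6 over the list alone), with camera adjusted p = 0.0594, against 0.0319 with scaling and 0.0269 without E12.5 replicate 1. The fallers were 7 without E12.5 replicate 1 and 2 without A6m replicate 3. Cox8b rose from 20.3 ± 4.33 to 184 ± 32.0 TPM, Prlr from 135 ± 18.4 to 536 ± 24.1 TPM and the retinol dehydrogenase gene Rdh5 from 88.4 ± 14.6 to 268 ± 30.2 TPM. Folr1 fell from 1357 ± 51.8 to 1011 ± 44.2 TPM (log2 difference -0.42, adjusted p = 0.0261), a call lost without any 1 of the 3 P14 or 3 A6m libraries (adjusted p = 0.0508 to 0.0860). Igf2 fell from 1074 ± 93.1 to 862 ± 46.6 TPM (log2 difference -0.32, adjusted p = 0.0103, and 0.0839 with scaling) and Gmnc from 61.2 ± 4.59 to 37.4 ± 0.791 TPM (log2 difference -0.69, adjusted p = 0.00114). Aqp1 was at 296 ± 18.0 and 176 ± 2.72 TPM (adjusted p = 0.0733, but 0.0278 with scaling, 0.0473 without the 10 most abundant genes, 0.0430 with quantile normalization, and 0.00319 and 0.00754 without E12.5 replicate 1 or 3), Otx2 at 387 ± 7.02 and 401 ± 12.6 TPM (adjusted p = 0.837) and Shh at 0.128 ± 0.0525 and 0.1004 ± 0.0317 TPM (adjusted p = 0.904).

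Endothelial markers fell in 18 of 19 cases (0 and 19 over the list alone; camera adjusted p = 4.89e-11, estimated-correlation adjusted p = 0.248). Kdr, encoding a vascular endothelial growth factor receptor, went from 21.4 ± 2.10 to 5.97 ± 0.377 TPM and Emcn from 39.0 ± 6.16 to 10.3 ± 3.65 TPM. Among mural cell markers 0 of 10 members rose and 8 fell (0 and 9 over the list alone, camera adjusted p = 4.98e-05, estimated-correlation adjusted p = 0.248). The pericyte gene Rgs5 fell from 71.0 ± 11.9 to 12.9 ± 3.44 TPM. In the list of fibroblasts and matrix 0 of 22 members rose and 13 fell (0 and 16 over the list alone, camera adjusted p = 2.68e-10, estimated-correlation adjusted p = 0.248). Postn fell from 83.3 ± 1.48 to 16.4 ± 0.610 TPM and Col1a1 from 9.33 ± 2.23 to 1.33 ± 0.493 TPM. Of the imprinted growth network 0 of 19 members rose and 10 fell (1 and 12 over the list alone, camera adjusted p = 3.77e-06, estimated-correlation adjusted p = 0.248). Ndn fell from 10.9 ± 0.217 to 1.06 ± 0.0386 TPM. Proliferation genes fell in 22 of 42 cases (0 and 24 over the list alone; camera adjusted p = 1.97e-07, estimated-correlation adjusted p = 0.248). Mki67 went from 1.58 ± 0.251 to 0.312 ± 0.131 TPM (log2 difference -0.98, adjusted p = 1.92e-04). For multiciliated cell regulators 0 of 17 members rose and 8 fell (1 and 9 over the list alone, camera adjusted p = 0.00823, estimated-correlation adjusted p = 0.397). Deup1 fell from 3.74 ± 0.585 to 0.836 ± 0.153 TPM. Axoneme genes had no camera call at this step: 13 of 62 members rose and 9 fell (14 and 10 over the list alone, camera adjusted p = 0.238), or 7 and 7 without A6m replicate 3. Cfap65 rose from 15.2 ± 1.93 to 37.5 ± 6.93 TPM and Ccdc40 fell from 5.38 ± 0.423 to 2.29 ± 0.566 TPM. The dynein assembly factors had a camera call upward (camera adjusted p = 0.0354, estimated-correlation adjusted p = 0.865) although 1 of 13 members rose and 0 fell (0 and 0 over the list alone) as deposited, the riser being Zmynd10 from 10.6 ± 0.962 to 14.1 ± 1.21 TPM. After scaling 6 rose (camera adjusted p = 0.0175). That list call was lost without A6m replicate 3 (adjusted p = 0.0597), and the call of Zmynd10 without P0 replicate 1 or 2, A6m replicate 1 or 3 or any P14 replicate (adjusted p = 0.0519 to 0.143) and with a pseudocount of 5 (adjusted p = 0.0884).

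Genes of the sex chromosomes filled 5 of the places under the naming rule: Xist rose from 0.628 ± 0.158 to 151 ± 3.49 TPM. Ddx3y fell from 88.0 ± 6.97 to 0.275 ± 0.133 TPM, Eif2s3y from 58.7 ± 5.97 to 0.184 ± 0.149 TPM, Uty from 24.7 ± 2.71 to 0.372 ± 0.188 TPM and Kdm5d from 20.5 ± 0.379 to 0.274 ± 0.0386 TPM. The other rises were those of B4galnt3, a glycosyltransferase gene, from 0.0795 ± 0.0487 to 20.01 ± 3.85 TPM, and of Spink8, a protease inhibitor gene, from 0.750 ± 1.24 to 67.0 ± 69.5 TPM, where the A6m libraries held 31.5, 22.4 and 147 TPM. Without A6m replicate 3 the A6m mean of Spink8 was 26.9 TPM and that of Eif2s3y 0.108 TPM. Of 588 tested genes on the X chromosome 151 were called, of 16 on the Y chromosome 9, and of the other 16818 genes 3482 (20.7%). Camera called 11 of 33 lists (4 up, 7 down), none with an estimated correlation, where 5 had an unadjusted p under 0.05 and fry called 12. With limma array quality weights the gene count was 5650, and with a 1.5-fold minimum (limma treat) 488.

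**Figure D3:**
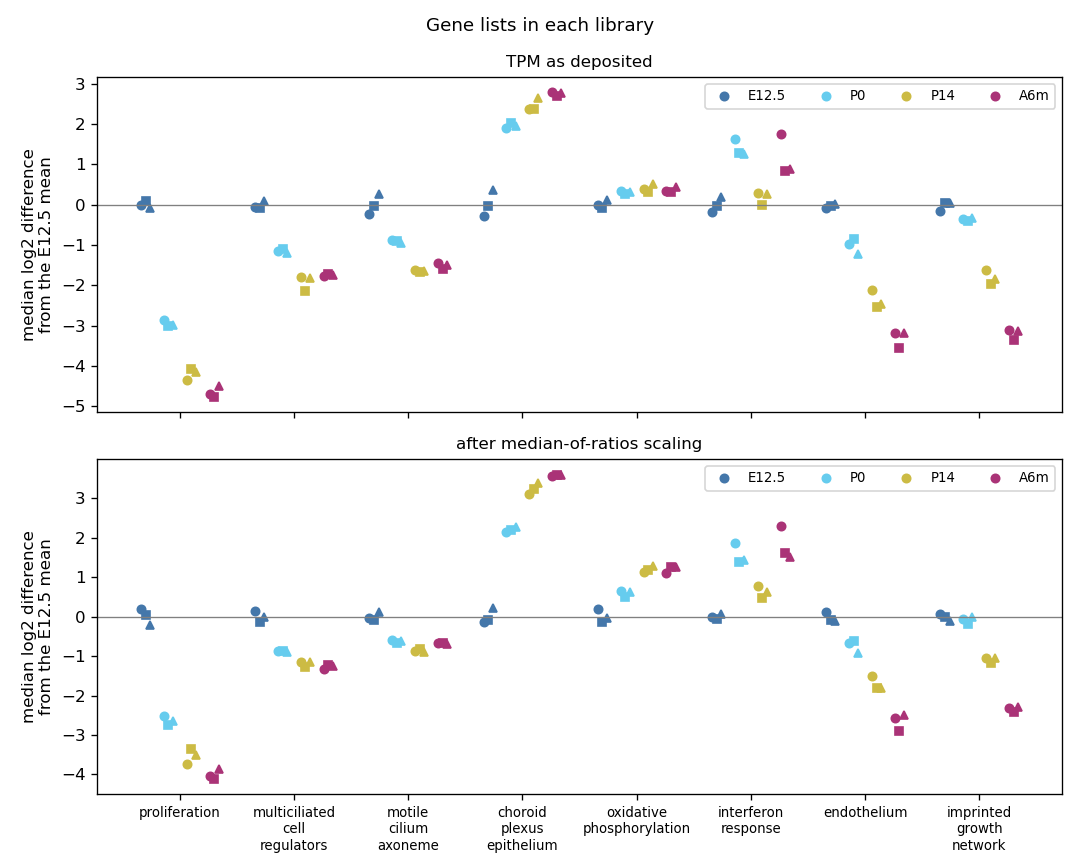
Median log2 difference of the members of 8 gene lists in each library from their E12.5 means, as deposited (upper panel) and after scaling (lower panel); colours mark the age, symbols the replicate, and 0 is the E12.5 mean. The proliferation list lies lowest at A6m, with a median of -4.59 as deposited and -3.98 after scaling, and the choroid plexus epithelium list highest, at 2.78 and 3.61.

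Over the whole span from E12.5 to 6 months the tissue gained secretory epithelial transcripts and lost those of cell division, the multiciliated cell program, endothelium and matrix. Kl rose from 1.28 ± 0.335 to 866 ± 51.1 TPM (676-fold, log2 difference 8.58, adjusted p = 1.44e-12) and Prlr from 0.668 ± 0.159 to 536 ± 24.1 TPM (803-fold, log2 difference 8.34, adjusted p = 1.49e-11). The folds are ratios of mean TPM, and the log2 differences are of TPM + 1. The former are larger here because the E12.5 means are near 1 TPM. Mki67 fell from 89.2 ± 10.6 to 0.312 ± 0.131 TPM (log2 difference -6.10, adjusted p = 2.51e-11), Shh from 19.7 ± 4.11 to 0.1004 ± 0.0317 TPM (log2 difference -4.22, adjusted p = 5.38e-10) and H19 from 1327 ± 146 to 2.89 ± 2.37 TPM (log2 difference -8.57, adjusted p = 1.15e-09).

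In the choroid plexus epithelium list 25 of 31 members rose and 2 fell (same over the list alone). By member, 30 rose and 1 fell after scaling (as deposited, camera adjusted p = 7.91e-20, estimated-correlation adjusted p = 0.268). Ttr rose from 15444 ± 5032 to 141048 ± 4602 TPM (log2 difference 3.24, adjusted p = 5.00e-08), Folr1 from 262 ± 55.5 to 1011 ± 44.2 TPM (log2 difference 1.97, adjusted p = 4.56e-08) and Enpp2 from 341 ± 91.3 to 29183 ± 1191 TPM. Other large rises under the naming rule were those of Ppp1r1b from 1.95 ± 0.360 to 532 ± 18.9 TPM and Cox8b from 0.264 ± 0.456 to 184 ± 32.0 TPM, and of Igkj3, a joining segment of the immunoglobulin kappa locus, listed at 0 in the E12.5 libraries and at 124 ± 31.1 TPM at A6m (adjusted p = 2.41e-10). Igkj3 is annotated from 70723223 to 70723260, a span shorter than a read of 100 bp. TPM adjusts for length, so few reads can give a high value, and the number of reads is unknown. Aqp1 was at 189 ± 91.8 TPM at E12.5 and 176 ± 2.72 TPM at A6m (adjusted p = 0.942), a log2 difference of 0.02 as deposited and 0.87 with scaling (adjusted p = 0.00263). Among ion and water transport genes 18 of 35 members rose and 13 fell (same over the list alone, camera adjusted p = 1.93e-07, estimated-correlation adjusted p = 0.410), and among organic solute transporters 25 of 37 members rose and 9 fell (same over the list alone, camera adjusted p = 1.21e-11, estimated-correlation adjusted p = 0.268). After scaling 26 ion and water transport genes rose and 4 fell, and 27 and 4 organic solute transporters. The sodium pump gene Atp1b1 rose from 45.3 ± 14.8 to 1078 ± 46.2 TPM and the iodide transporter gene Slc5a5 from 0.0675 ± 0.0222 to 15.7 ± 1.21 TPM.

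Of the oxidative phosphorylation genes 40 of 60 members rose and 3 fell (same over the list alone), and all 60 rose after scaling (as deposited, camera adjusted p = 3.29e-16, estimated-correlation adjusted p = 0.268). Without E12.5 replicate 2, 5 fell. The glycolysis genes included 11 that rose and 2 that fell of 17 (same over the list alone; camera adjusted p = 1.08e-08, estimated-correlation adjusted p = 0.268). Ldhb, encoding a lactate dehydrogenase subunit, rose from 129 ± 19.2 to 762 ± 6.64 TPM. For the interferon response 18 of 24 members rose and 1 fell (19 and 1 over the list alone, camera adjusted p = 7.54e-11, estimated-correlation adjusted p = 0.268), led by Ifi27 from 8.73 ± 0.933 to 563 ± 51.8 TPM, and for class I antigen presentation 10 of 15 members rose and 0 fell (same over the list alone, camera adjusted p = 1.96e-07, estimated-correlation adjusted p = 0.268).

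All 42 proliferation genes fell, as deposited and after scaling (camera adjusted p = 1.08e-11, estimated-correlation adjusted p = 0.268). Top2a went from 181 ± 4.29 to 0.459 ± 0.376 TPM. All 17 multiciliated cell regulators fell, 14 of them also after scaling (camera adjusted p = 1.51e-04, estimated-correlation adjusted p = 0.268). Cdc20b fell from 294 ± 39.6 to 0.326 ± 0.481 TPM, Mcidas from 37.0 ± 4.10 to 0.0520 ± 0.0483 TPM and Gmnc from 128 ± 23.3 to 37.4 ± 0.791 TPM (log2 difference -1.73, adjusted p = 6.79e-08, and -0.89 with scaling). The microRNA gene Mir449b, which lies within the bounds of Cdc20b, was at 329.6 ± 198 TPM at E12.5 and listed at 0 in all 3 A6m libraries. Its annotated span is shorter than a read of 100 bp, and whether its reads came from Cdc20b was not tested. In the motile axoneme list 1 of 62 members rose and 58 fell (same over the list alone) as deposited. By member, 9 rose and 41 fell after scaling (as deposited, camera adjusted p = 8.01e-05, estimated-correlation adjusted p = 0.566). Ccdc40 fell from 98.5 ± 21.1 to 2.29 ± 0.566 TPM and Dnah7a from 48.8 ± 4.74 to 1.06 ± 0.549 TPM. The dynein assembly factors fell in all 13 cases as deposited. By member, 2 rose and 9 fell after scaling (as deposited, camera adjusted p = 0.0146, estimated-correlation adjusted p = 0.512). For intraflagellar transport and the BBSome, which all cilia use, 0 of 40 members rose and 33 fell (0 and 34 over the list alone) as deposited, but 16 rose and 12 fell after scaling, and the camera direction turned from down (camera adjusted p = 0.0471, estimated-correlation adjusted p = 0.677) to up (adjusted p = 0.703). The call was also lost without E12.5 replicate 2 (adjusted p = 0.0578) or A6m replicate 3 (adjusted p = 0.0604).

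Of the imprinted growth network 1 of 19 members rose and 18 fell (same over the list alone, camera adjusted p = 5.61e-04, estimated-correlation adjusted p = 0.339). Slc38a4 fell from 40.2 ± 3.29 to 0.0786 ± 0.0784 TPM. Igf2 fell from 1079.6 ± 16.9 to 862 ± 46.6 TPM as deposited (log2 difference -0.33, adjusted p = 0.00155) but was higher with scaling, by 0.53 (adjusted p = 7.82e-04). Otx2 likewise had a log2 difference of -0.19 as deposited (adjusted p = 0.194) and 0.67 with scaling (adjusted p = 7.61e-06), and as deposited it was called lower without E12.5 replicate 1 (-0.36, adjusted p = 3.46e-04). All 19 endothelial markers fell on both scales (camera adjusted p = 3.13e-05, estimated-correlation adjusted p = 0.410), as did all 14 erythroid markers (camera adjusted p = 1.71e-04, estimated-correlation adjusted p = 0.404). Hbb-y went from 24778 ± 4462 to 22.0 ± 29.6 TPM, Hba-x from 7065 ± 408 to 7.82 ± 11.7 TPM and Hbb-bh1 from 3907 ± 1904 to 3.23 ± 4.46 TPM, and A6m replicate 3 alone held 56.2, 21.3 and 8.38 TPM of them. Without A6m replicate 3 the A6m means were 4.87, 1.08 and 0.660 TPM for these globins, 1.54 for H19, 0.0484 for Cdc20b, 0.0303 for Mcidas, 0.250 for Top2a and 0.0334 for Slc38a4, all further below E12.5, and all 8 calls held. In the list of fibroblasts and matrix 3 of 22 members rose and 18 fell (same over the list alone, camera adjusted p = 0.0230, estimated-correlation adjusted p = 0.566). Col3a1 fell from 493 ± 50.1 to 3.09 ± 0.967 TPM. Of the mural cell markers 0 of 10 members rose and 9 fell (same over the list alone), without a camera call as deposited (adjusted p = 0.129) but with one after scaling (adjusted p = 0.0171). In the Hedgehog list 1 of 14 members rose and 13 fell (same over the list alone, camera adjusted p = 0.0228, estimated-correlation adjusted p = 0.512). Camera called 22 of 33 lists (10 up, 12 down), none with an estimated correlation, where 5 had an unadjusted p under 0.05 and fry called 30. A 1.5-fold minimum (limma treat) left 8436 called genes.

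**Figure D4:**
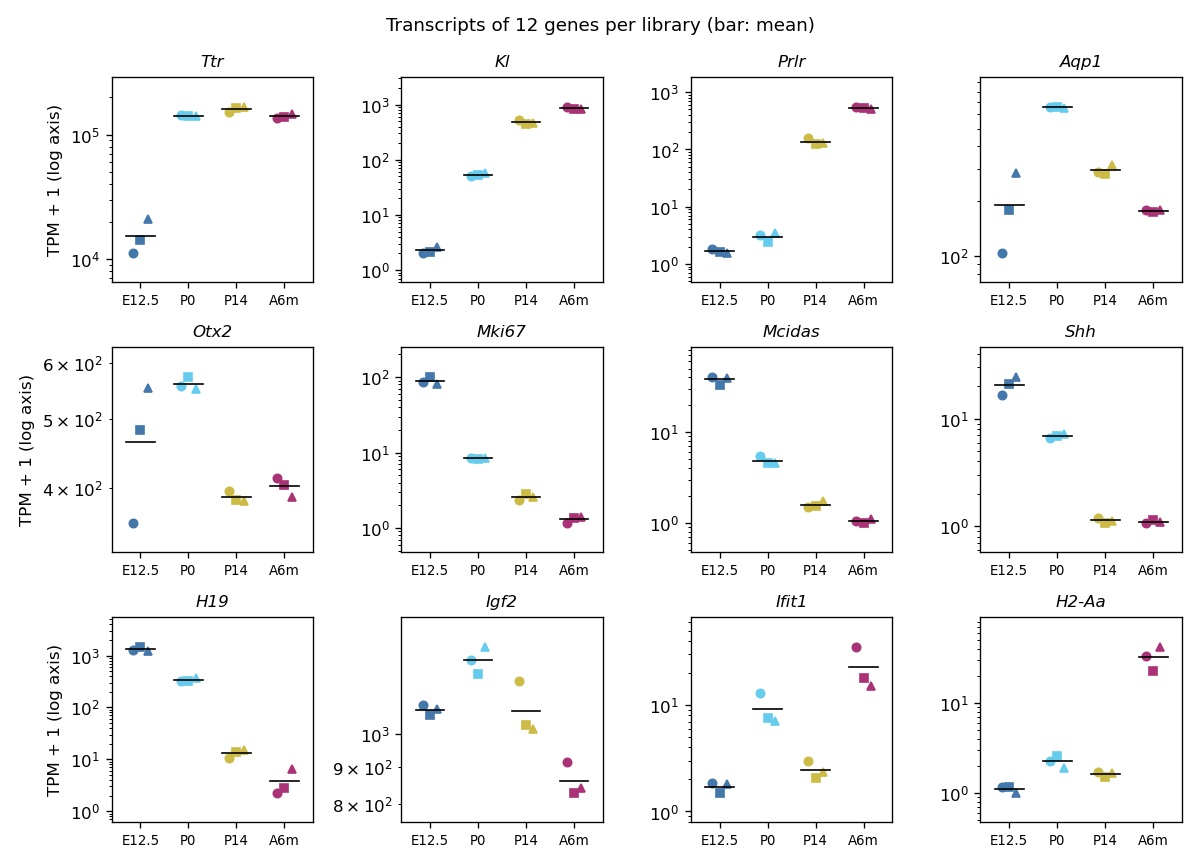
TPM + 1 of 12 genes at the 4 ages on log axes, with 1 point per library, symbols for the replicate and a bar at the mean. Kl went from 1.28 ± 0.335 to 866 ± 51.1 TPM and Mcidas from 37.0 ± 4.10 to 0.0520 ± 0.0483 TPM between E12.5 and A6m.

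Some genes rose into 1 age and fell after it. Of 3233 genes that rose from E12.5 to P0, 1495 fell from P0 to P14 as deposited, against 1728.8 if both steps were independent, and 959 with scaling, against 1000.1. Around P14, 113 genes rose and then fell, against 112.5, and 458 with scaling, against 552.9. With no effect simulated 20 times, no gene rose and then fell around either age, which sets no limit where both steps hold real effects. The libraries of the middle age enter both steps with opposite sign, so the steps are not independent even without effects. The covariance of their log2 differences was then -0.043 around P0 and -0.044 around P14, against 0.032 and 0.033 observed. The counts for independent steps are thus a reference and not an exact expectation. Both counts fell with a 1.5-fold minimum (limma treat), to 183 around P0 and 5 around P14. The opposite order, a fall and then a rise, was called for 191 genes around P0 and 590 around P14, against 405.6 and 818.1 if the steps were independent. With scaling P0 had more, 739 against 387 around P14, where 1227.3 and 523.8 would be independent. Slc6a20a was among those that rose to P0 and then fell, from 82.1 ± 9.92 to 34.1 ± 1.99 TPM, and it rose again to 67.1 ± 6.67 TPM at A6m.

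In the GENCODE M21 annotation of GRCm38, Ttr lies on chromosome 18 from 20665280 to 20674321 on the plus strand, Kl on chromosome 5 from 150952607 to 150993817 on the plus strand, and Folr1 on chromosome 7 from 101858331 to 101870788 on the minus strand. Aqp1 lies on chromosome 6 from 55336432 to 55348555 (plus), Prlr on chromosome 15 from 10177238 to 10349180 (plus), Otx2 on chromosome 14 from 48657677 to 48673819 (minus), Shh on chromosome 5 from 28456815 to 28467256 (minus) and Gmnc on chromosome 16 from 26913553 to 26991652 (minus). The imprinted neighbours H19 (142575529 to 142578143) and Igf2 (142650766 to 142666816) lie on the minus strand of chromosome 7, where Mki67 lies from 135689784 to 135716361. The multiciliated cell genes Ccno (112987802 to 112990777), Mcidas (112993845 to 113000394) and Cdc20b (113035111 to 113091195) are neighbours on the plus strand of chromosome 13, and Mir449b lies there from 113037419 to 113037498. All are protein-coding genes except H19, annotated as lincRNA, and Mir449b, annotated as miRNA, and the values are per gene symbol and do not separate exons or transcript forms.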

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

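List medians under other settings, and counts without 8 ribosomal RNA-associated features or without X and Y genes, were chosen after seeing the data. Of 243 recomputed counts of genes and lists, many of them with 1 library left out, 227 stayed within 1.5 times the main count. That measure takes totals and ignores direction. Between P14 and P0, scaling and quantile normalization stayed within it (7409 and 6929 genes against 10244). The genes called higher nevertheless went from 928 to 3956 and 3525. Rise-then-fall counts moved with scaling to 959 around P0 and 458 around P14, the latter also to 393 with quantile normalization, 231 without the 10 most abundant genes and 201 with array quality weights, which also gave 5650 genes for A6m against P14. Against a 1.5-fold difference limma treat called 3983, 1626, 488 and 8436 genes in the 4 comparisons and 183 and 5 that rose and fell, by construction fewer. Estimated inter-gene correlations left 0, 0, 0 and 0 lists called (lowest adjusted p 0.275, 0.385, 0.137 and 0.268), while fry called 31, 26, 12 and 30. For the other moves the cause was not tested.

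Igf2 reversed from P0 to P14 with scaling (0.28) and quantile normalization (0.0108), and from E12.5 to A6m with scaling (0.53), without the 10 most abundant genes (0.16) and with quantile normalization (0.37). Otx2 reversed from E12.5 to A6m under the same 3 settings (0.67, 0.30 and 0.32), and Folr1 from P0 to P14 with scaling (0.45). The call of Zmynd10 from P14 to A6m was lost with the replicate block (adjusted p = 0.0609). Medians of called lists from P0 to P14 reversed with scaling for ion and water transport (0.20), organic solute transporters (0.26), glycolysis (0.42), cholesterol synthesis (0.38) and neurons (0.0642), and from E12.5 to A6m for epithelial junctions (0.60). Scaling and the rescaling multiply each library by 1 factor, so by construction they turn values smaller than the shift they give to all genes (medians -0.41 to 0.00 and -0.71 to -0.01 with scaling). For quantile normalization the cause was not tested. Of 153 named differences, 139 kept direction and side of the threshold under all 18 settings. These settings left out the other filters, the array quality weights, treat and the fits of 6 libraries alone. The differences that changed were those of Igf2, Otx2, Aqp1, Folr1 and Gmnc, named in every comparison, and of Zmynd10. Most of the rest had been picked as called differences in these data, which favours stability, so the 139 do not speak for other genes.

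Leaving out each library in turn gave 9894 to 11334, 8774 to 11084, 2638 to 4631 and 12788 to 13712 genes in the 4 comparisons, and 14470 to 15092 over the 4 ages. It gave 1151 to 1783 and 80 to 154 genes that rose and fell, and 18 to 22, 19 to 21, 11 to 14 and 21 to 23 lists. Without E12.5 replicate 1 the counts were 11334, 11084, 4631 and 13712. Leaving out the 8 ribosomal RNA-associated features gave 11717, 10907, 4335 and 13969 genes, and leaving out X and Y genes 10472, 9893, 3478 and 12999. With the replicate block the counts were 10568, 9897, 3162 and 13334 genes, 14665 over the 4 ages, 1419 and 99 that rose and fell, and 21, 20, 11 and 22 lists. The numbers do not pair the samples: residuals of libraries with the same number had a mean r of -0.00544 (18 pairs). Only the 6 libraries of a pair cannot serve the tests over more ages, and treat has no F-test, so neither was run there. Depth is unknown, so what it limits cannot be stated.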

Other observations

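The tests of A6m replicate 3 against adult blood, of calls outside the sex chromosomes, of the axoneme genes and of the splits of each pair of ages were chosen only after the result was seen. Of the lists described nowhere above, the circadian clock had the lowest camera p between E12.5 and P0: 15 of 18 members rose and 1 fell (same over the list alone, camera adjusted p = 3.88e-08, estimated-correlation adjusted p = 0.275). Nr1d1 rose from 1.17 ± 0.306 to 8.15 ± 1.77 TPM. From P14 to A6m the clock list was not called: 6 of 18 members rose and 4 fell (6 and 5 over the list alone, camera adjusted p = 0.822). Arntl fell from 7.39 ± 0.346 to 2.75 ± 0.0691 TPM while Dbp rose from 25.1 ± 0.165 to 56.7 ± 9.69 TPM. The time of day of the dissections is not given. Mitochondrially encoded genes rose from E12.5 to A6m, as 13 of 15 members rose and 0 fell (same over the list alone, camera adjusted p = 2.08e-10, estimated-correlation adjusted p = 0.268). In the hindbrain Hox list 0 of 10 members rose and 10 fell (same over the list alone) over the same span (camera adjusted p = 0.0230, estimated-correlation adjusted p = 0.467). Meis2 fell from 54.6 ± 6.12 to 6.36 ± 0.405 TPM. Of the forebrain list 2 genes were tested, too few for camera: Emx1 rose from 0.0719 ± 0.0904 to 4.69 ± 0.534 TPM and Lhx2 fell from 1.30 ± 0.263 to 0.00487 ± 0.00844 TPM. In the BMP and Wnt list 5 of 28 members rose and 22 fell (same over the list alone) as deposited. By member, 10 rose and 14 fell after scaling (as deposited, camera adjusted p = 0.173). Wnt5a fell from 141 ± 35.4 to 2.21 ± 0.546 TPM. In the Notch list 1 of 17 members rose and 14 fell (same over the list alone) from E12.5 to P0 (camera adjusted p = 0.0379, estimated-correlation adjusted p = 0.463), where Dlk1 rose from 30.6 ± 4.98 to 132 ± 16.7 TPM. The Notch list call was lost without the 8 ribosomal RNA-associated features (adjusted p = 0.0570). For immediate early genes 1 of 16 members rose and 11 fell (1 and 12 over the list alone) at that step (camera adjusted p = 0.0431, estimated-correlation adjusted p = 0.459). The call was lost without E12.5 replicate 1 (adjusted p = 0.0888) or without those 8 features (adjusted p = 0.0624). Myc fell from 8.76 ± 1.96 to 1.05 ± 0.0573 TPM. For tubulin-modifying and severing enzymes 1 of 27 members rose and 23 fell (same over the list alone) from E12.5 to A6m, and 8 rose and 12 fell after scaling, with medians of -0.80 and -0.16 (as deposited, camera adjusted p = 0.109).

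Markers of neural cells moved in different directions. In the neural progenitor list 0 of 10 members rose and 10 fell (same over the list alone) from E12.5 to A6m (camera adjusted p = 0.0271, estimated-correlation adjusted p = 0.467). Nes, encoding nestin, fell from 59.4 ± 7.03 to 0.673 ± 0.187 TPM. Of the neuronal markers 1 of 16 members rose and 12 fell (same over the list alone, camera adjusted p = 0.965). Tubb3 fell from 25.7 ± 22.6 to 0.522 ± 0.105 TPM. Astrocyte markers went both ways, as 5 of 11 members rose and 5 fell (5 and 6 over the list alone, camera adjusted p = 0.129): Aldh1l1 rose from 2.35 ± 0.536 to 48.5 ± 2.78 TPM and Gja1 fell from 104 ± 21.9 to 4.62 ± 0.983 TPM. Of the oligodendrocyte markers 2 of 7 members rose and 1 fell (same over the list alone, camera adjusted p = 0.0652). Mbp rose from 8.24 ± 0.673 to 17.5 ± 1.86 TPM. From P14 to A6m 1 of 7 members rose and 4 fell (1 and 5 over the list alone), but 0 rose and 1 fell without A6m replicate 3. Markers of ependyma outside the axoneme list fell in 9 of 14 cases from P14 to A6m (1 and 9 over the list alone; camera adjusted p = 7.96e-05, estimated-correlation adjusted p = 0.248). Mia went from 219 ± 18.2 to 49.3 ± 4.86 TPM. Of these 14 genes 7 stand in another list and 13 reached at least 1 TPM in every A6m library, and of 11 astrocyte genes 6 and 10. Of 31 choroid plexus epithelium genes 9 also stand in another list, and of 35 ion and water transport genes 7. Trpv4 is in both of these lists, so their results are not independent. Camera sets a list against all other genes, and for 2, 10, 7 and 6 lists of the 4 comparisons its direction differed in sign from the list's median or mean. Of these, 0, 5, 0 and 1 were called: ion and water transport, organic solute transporters, glycolysis, cholesterol synthesis and neurons (median -0.18, direction up, camera adjusted p = 0.00780, estimated-correlation adjusted p = 0.734, and 0.688 with scaling) from P0 to P14, and epithelial junctions (median -0.17, direction up, camera adjusted p = 0.0153, estimated-correlation adjusted p = 0.498) from E12.5 to A6m.

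A6m replicate 3 held a trace of embryonic transcripts. Its Hbb-y, Hba-x and Hbb-bh1 stood at 56.2, 21.3 and 8.38 TPM, against 6.17 and 3.56, 1.45 and 0.709, and 0.814 and 0.506 TPM in A6m replicates 1 and 2. Over 92 other genes high at E12.5 and low at A6m, its median excess over the other A6m libraries was 0.216% of the E12.5 level (quartiles 0.0566 to 0.474, with 66 of 92 above both others), near the 0.207% of the globin genes, against -0.0374% and -0.0825% in replicates 1 and 2 over 78 and 75 genes chosen in the same way, though the range tested had been set from 9 genes seen before and left out. Adult blood is argued against, since the ratio of Hba-x to Hba-a2 was 8.65 times the highest of the other A6m libraries. RNA or reads of an E12.5 library in A6m replicate 3 may account for the trace, and no other biological source was tested.

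The age of the A6m animals goes with their apparent sex. Genes that escape X inactivation had a median log2 difference from P14 to A6m 0.67 above that of all genes. Among them Kdm6a, Kdm5c, Ddx3x and Eif2s3x were called and 5530601H04Rik was not (adjusted p = 0.399). A part of the calls on the X and Y chromosomes may thus owe to sex. Of the tested genes 56.25% on the Y chromosome and 25.7% on the X chromosome were called, against 20.7% elsewhere. For the 3482 calls on other chromosomes, sex and age cannot be told apart, because every A6m library had Xist and every P14 library had transcripts of the Y chromosome.

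Axoneme genes fell from E12.5 to A6m. The authors' normalization, with Ttr and mitochondrial transcripts taking more of the TPM, is argued against as the whole cause, since the median after scaling was -0.67 (quartiles -1.53 to -0.15) with 41 members falling and 9 rising. Fewer ependymal cells in the tissue cannot be told apart from other causes: ependymal markers outside the axoneme had a median of -0.00238 from E12.5 to P0 (quartiles -0.55 to 1.37) and -1.03 from E12.5 to A6m (quartiles -3.66 to 1.70). A first version of that test used the step to P0 alone and counted against fewer ependymal cells. The step to A6m was added after that value was seen. From P14 to A6m the ependymal markers had a median of -0.72 (9 of 14 fell) and the axoneme genes one of 0.036. The markers and the axoneme genes thus did not move together at that step. Of the 14 markers 7 also stand in another list, such as that of astrocytes, so they may not track ependymal cells alone. Cells on their way to ciliation at E12.5 that are absent later also stay open, as age and such cells are the same split here, and the median from P14 to A6m after scaling was 0.0853, not a further fall.

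Splits of the 6 libraries of a pair of ages into other groups of 3 number 10, so the share can never be under 0.1. For genes the real split was 1 of 10 as large in each comparison, with 10848, 10244, 3642 and 13446 calls against at most 10, 3, 4 and 2. For lists, 2, 1, 4 and 1 of the 10 splits called as many, where the real counts were 21, 20, 11 and 22 and the highest others 21, 15, 14 and 21, so a count of camera calls at the preset correlation was also reached by other splits for P0 against E12.5 and for A6m against P14. Over the 4 ages only the real split, 1 of 100, called as many as 14829 genes (highest other 10436). The 1495 that rose and fell around P0 were also reached by 1 of 100 (highest other 433), but independent steps would give 1728.8. Splits that mix ages put differences between ages into the spread within groups. These shares thus show that libraries group by age, and they do not test whether genes rise and then fall. Around P14 3 of 100 splits called at least the real 113, which is near the 112.5 that independent steps would give. The highest other split, drawn 2 times, called 8037 genes, which points to a structure of the samples: it kept the 3 ages whole in another order (A6m, P0, P14). Splits that mixed ages called at most 3.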
